A study of Homo sapiens with 8 samples.

How the data were processed

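The study measured RNA bound by ALKBH5 in the human beta cell line EndoC-βH1 with eCLIP after ultraviolet crosslinking. The labels give 4 IP and 4 input libraries under the replicate names N1, N2, A3 and B3, in 2 batches. They do not state that the input was size-matched, or that the replicates were separate cultures. The extraction protocol and the series text name different ALKBH5 antibodies, and which was used is open.

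According to the labels the authors trimmed reads with fastp, aligned them with STAR to GRCh38 and counted them with deepTools. Versions, parameters and the handling of multi-mapped and duplicate reads were not given in the sources used here. The authors deposited counts, which are raw read counts without strand for 65832184 bins of 50 nt on 706 sequences. These were whole numbers, and 27018867 bins had a count in some library. Total counts were 108644360, 111970951, 110495581 and 107441345 for input N1, N2, A3 and B3 and 120608288, 125555165, 106981974 and 101327835 for the IPs in the same order. The 100 highest bins of a library held 12.3% to 25.9% of its counts, and copies of repeated genes hold similar counts, so values of near-identical genes are uncertain.

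The authors also deposited 1 peak list per pair, named after the peak caller Piranha. In these deposited lists the score is the IP count of the bin or the mean over the peak's bins. A further deposited column is the p-value of the peak, all under 0.05, and another is the natural log (ln) of the input count plus 1. The score and the log were checked against the count table in the peaks of a single bin. The strand column held a plus sign throughout and was not used.

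Gene positions came from a RefSeq annotation of GRCh38 that gave gene spans without strand or exons, with 59716 genes on the 25 chromosomes. A bin was assigned to a gene when its midpoint lay in the span of exactly 1 gene. Exons had been intended in place of spans. The 1783623 bins in several genes were left out. Tests of exons and introns apart, shares of untranslated and coding regions, and the search for the DRACH motif of m6A were not run because no exons and no genome sequence were used here. INS and the other genes without bins of their own were counted with their overlapping bins, a setting named where it is used.

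Counts per gene were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood test) with the batch as a covariate, and the fold is IP over input. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values are CPM with the SD over n = 4 libraries, and log2 CPM used a prior count of 2. The difference between batches was tested as an interaction. Gene lists were tested with camera of limma 3.58.1 with a correlation of 0.01, and again with an estimated correlation. With the estimated correlation 0 lists passed. RNA class shares were compared by an exact two-sided permutation test over 70 relabellings, which can reach 0.0286, and by exact sign flips over the 4 pairs, which can reach 0.125. Each bin was put in 1 class, and the p-values were adjusted over the classes.

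Peaks on the 25 chromosomes were merged over the 4 lists where they shared at least 1 base. Counts in regions present in at least 2 lists were tested with edgeR in the same way, with library sizes from all bins and scaling factors taken from the gene counts. The factors' source was chosen after the files were seen, and factors from the regions themselves are given as an alternative.

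The genes named were set by a rule written before the data were examined, as were the planned tests and the gene lists. Some tests were added later, among them those of tRNA genes and of summed snRNA copies. Among genes past the threshold with at least 10 CPM on average and the same direction in 4 pairs, the 12 largest and 12 smallest log2 fold changes were named. ALKBH5, INS, the 8 largest regions present in all 4 lists and any list member could be named as well, and the values of some members are not reported here. The lists were beta cell identity, secretory granule and exocytosis, m6A machinery, unfolded protein response, interferon and antigen presentation, SR and hnRNP splicing factors, nuclear non-coding RNA, proliferation, apoptosis and p53, other pancreatic and stromal cell types, cytosolic ribosomal proteins, mitochondrial mRNA, nuclear OXPHOS subunits, replication-dependent histones and protein-coding genes over 100 kb. Mitochondrial genes were matched by the annotation's own symbols.

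IP and input of the same name were checked for shared deviations from their group means. The correlation across genes, which are not independent replicates, was 0.544, 0.537, 0.573 and 0.688 for N1, N2, A3 and B3. Within batch B1 the names were not told apart (0.532 and 0.534 between N1 and N2), so much of this is the batch there. Within batch B2 they were told apart, with 0.175 and 0.127 between A3 and B3. The main fit holds the batch and no term for the pair. The replicate name was used as a block in an alternative.

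The test was also run on simulated data with known changes. Of 100 genes changed 2-fold among 26424, 53 were found, and of 100 changed 4-fold, 100 were found, with 4 other genes called. The changed genes were drawn from those with a mean fitted count over 100, and no pair effect was simulated. The recovery therefore holds for well-covered genes only. For regions, 10 of 100 were found at 2-fold and 87 at 4-fold among 19926, with 3 others called. The alternatives were the replicate block, no batch term, other size factors, total counts only, DESeq2 1.42.0, other count filters, other assignments of shared bins, each pair left out, each batch alone, stricter peaks and another overlap of peaks. Alternatives added after the data were seen left out the 4 highest bins of each gene, added a smooth term of gene span, gave shared bins to the shortest gene, took region-based factors, and took shares over the 25 chromosomes alone. The peak lists without each pair in turn were added as well. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.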

Results

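ALKBH5 is an enzyme that removes the methyl group of N6-methyladenosine (m6A), a common modification of messenger RNA. The study asked which RNAs this protein binds in EndoC-βH1, an insulin-producing human pancreatic beta cell line, and used eCLIP for it. In eCLIP, ultraviolet light crosslinks proteins to the RNA they touch, an antibody pulls down the protein of interest, and the attached RNA fragments are sequenced next to an input library made without the antibody step. There were 4 immunoprecipitated libraries (IP) and 4 input libraries (n = 4 per group), which share the replicate names N1, N2, A3 and B3. The labels place N1 and N2 in batch B1 and A3 and B3 in batch B2. Counts were deposited for 50-nt bins along the genome, with 101327835 to 125555165 counts per library. Of these, 34.2% to 42.5% lay on sequences other than the 25 chromosomes (22 autosomes, X, Y and the mitochondrial chromosome). Between 29.6% and 41.6% of the counts of a library fell in bins that belonged to exactly 1 annotated gene. Each pair of libraries also came with a deposited list of ALKBH5 peaks. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

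The first question was which classes of RNA were gained or lost between input and IP. Small nuclear RNAs (snRNA) are mostly RNA parts of the spliceosome, and this class also held RN7SK, which is not. They took 2.74% ± 1.63 (SD, n = 4) of the input counts and 0.378% ± 0.164 of the IP counts. The other small RNAs, which include the Y RNAs, the 7SL RNA of the signal recognition particle and the RNase P and MRP RNAs, went from 0.761% ± 0.135 to 0.106% ± 0.0399. Small nucleolar RNAs (snoRNA), which guide the modification of ribosomal RNA, went from 1.14% ± 0.759 to 0.459% ± 0.365. These 3 classes had a lower share in the IP in all 4 pairs. Protein-coding genes went from 25.7% ± 3.22 to 32.9% ± 2.56 of the counts, mitochondrial RNA from 1.63% ± 0.827 to 2.67% ± 0.687 and tRNA from 0.0560% ± 0.0431 to 0.105% ± 0.0892, each with a higher share in the IP in 4 of 4 pairs. Ribosomal RNA annotated on the chromosomes took 13.7% ± 1.08 of the input and 12.7% ± 0.883 of the IP. Counts on other sequences formed a class of their own, so any ribosomal RNA encoded there was not counted as such. The same holds for the RNA classes above. The exact two-sided permutation test gave p = 0.0286, the smallest value that 4 against 4 libraries allow, for snRNA, the other small RNAs and protein-coding genes. After adjustment over the 11 classes tested this became 0.105 in the permutation test, so no class passed the threshold. The mitochondrial and snoRNA shares gave p = 0.143 and 0.200 in the same exact test (adjusted p = 0.262 and 0.275). Within batch B1 the IP minus input difference was -3.63 percentage points for snRNA and 5.86 points for protein-coding genes, and within B2 it was -1.10 and 8.56 points. The 95% Wilson interval of a share in 1 library reached at most 0.00935 percentage points to either side, and such intervals cover counting error only.

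**Figure D1:**
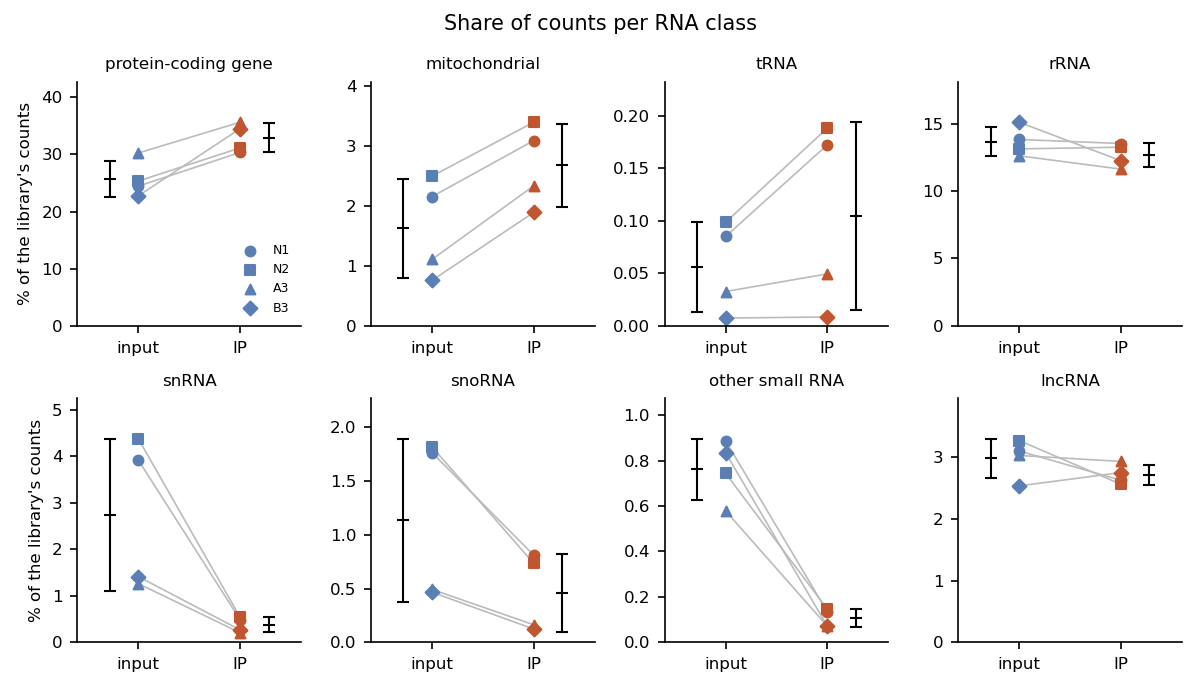
Share of each library's counts (%) in 8 RNA classes, for the 4 input and the 4 IP libraries. Symbols mark the replicates, grey lines join the input and IP of a pair, and the bars beside the points give mean ± SD (n = 4). The snRNA share was 2.74% in the input and 0.378% in the IP on average, and the protein-coding share 25.7% and 32.9%.

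The next comparison asked which single genes had more or fewer counts in the IP than in the input. Of 27003 genes tested, 3674 had more counts in the IP than in the input and 1978 had fewer (edgeR, adjusted p under 0.05), and of these 2170 and 620 differed by at least 2-fold. The direction was the same in all 4 pairs for 3652 of the higher and 1950 of the lower genes. Among 16114 protein-coding genes 2762 were higher and 1335 lower, and among 7549 long non-coding RNA genes 453 were higher and 339 lower. Of 45 snRNA genes 34 were lower and 1 was higher, with a median log2 fold change of -2.44. Of 25 snoRNA genes 15 were lower and 1 higher, and of 15 ribosomal RNA genes 13 were lower and 0 higher. Only genes with bins of their own were tested, so these may not stand for their classes. The share of ribosomal RNA in all counts changed far less, from 13.7% to 12.7%. The 232 tRNA genes went both ways, with 32 higher and 20 lower. The replicate name as a block gave 5322 higher and 3526 lower genes. The split of the calls depended on the scaling: 65% of the calls were higher with the TMM factors, and 93.9% were higher (5815 against 380 lower) with total counts only, where the median of all genes was 0.31 instead of -0.02 on the log2 scale.

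The number of calls also depended on single pairs and on the batch. Without pair N1 there were 1555 higher and 427 lower genes, without N2 1179 and 291, without A3 4305 and 2981, and without B3 4747 and 3122. Batch B1 alone gave 4646 higher and 3162 lower genes, and batch B2 alone gave 0 and 0 by edgeR, with 5881 genes at an unadjusted p under 0.05 (no other tool was run on that batch). Across genes the log2 fold changes of B1 and B2 correlated with r = 0.632 (genes are not independent replicates), and 74.5% of the 26095 genes tested in both batches had the same direction. A test of the difference between batches called 0 of 27003 genes with edgeR (smallest adjusted p = 0.071). In that test 2276 genes had an unadjusted p under 0.05 where 1350 would be expected by chance, and DESeq2 called 133.

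The 12 genes with the largest gains among well-covered genes were led by MC1R, the melanocortin receptor of pigment cells, on chromosome 16 (89918862 to 89920972, GRCh38). Its level went from 4.19 ± 0.619 CPM in the input to 59.7 ± 14.4 CPM in the IP (SD, n = 4), a log2 fold change of 3.82 ± 0.22 (SE, adjusted p = 2.44e-05 in edgeR). KIFC2, a kinesin motor (3.56 ± 0.33), RHOT2, a GTPase of mitochondrial transport (3.23 ± 0.24), and ISYNA1, which makes inositol phosphate (2.97 ± 0.42), were among the better covered, at 293 ± 146, 138 ± 38.5 and 190 ± 109 CPM in the IP. The other members were CAPS (3.13), the receptor gene OXER1 (2.93), the scaffold gene NHERF4 (2.86), the long non-coding RNA SNTG2-AS1 (2.82), HMG20B, part of a chromatin repressor complex (2.81), the kinase gene ULK3 (2.78), AP1G2, a subunit of a vesicle coat adaptor (3.60), and the asparagine tRNA gene TRN-GTT3-1 (2.76). Their adjusted p-values ran from 2.44e-05 to 0.0123 in edgeR, and all 12 were higher in 4 of 4 pairs. In AP1G2, 94.3% of the counts came from 4 bins, and without them its log2 fold change was 0.43 (adjusted p = 0.263). TRN-GTT3-1 missed the threshold without N1 (adjusted p = 0.0908) and without N2 (0.0793) in edgeR, with log2 fold changes of 2.75 and 2.95. As tRNA genes have near-identical copies, which copy gained the reads is uncertain.

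The 12 largest losses were in genes and pseudogenes of small RNAs and in genes with nearly all their counts in 4 bins. RNY5, a Y RNA of the Ro particle on chromosome 7 (148941488 to 148941571), went from 1428 ± 769 to 18.1 ± 13.3 CPM, a log2 fold change of -6.47 ± 0.28 (adjusted p = 6.84e-06 in edgeR). The genes of U1, the snRNA that recognises the 5′ splice site, had fewer counts as well: RNU1-2 gave -4.93 ± 0.25, from 10236 ± 3248 to 349 ± 139 CPM, and RNU1-1 -4.85 ± 0.24, from 5617 ± 2584 to 204 ± 111 CPM. The U4 gene RNU4-2 gave -5.00 ± 0.29. The U1 pseudogenes RNU1-7P (-5.08), RNU1-63P (-4.85) and RNU1-89P (-4.52) may share reads with the U1 genes, so which copy lost the reads is uncertain. The long non-coding genes LOC105378179 (-4.88) and LOC124904013 (-4.99) hold 99.3% and 99.0% of their counts in 4 bins each, some of them within 100 nt of the 7SL gene RN7SL2 and the U4 pseudogene RNU4-27P. Without those bins LOC105378179 gave -2.02 (adjusted p = 0.000489 in edgeR) and LOC124904013 had too few counts to test. SPATA21 (-5.38), the cell cycle inhibitor gene CDKN1A (-5.24) and LOC102724945 (-5.10) hold 98.5%, 98.7% and 97.5% of theirs in 4 bins with no annotated small RNA within 100 nt. Without those bins the values were -1.10 (adjusted p = 0.0101), -1.11 (0.0998) and -0.76 (0.0105) in edgeR, so CDKN1A missed the threshold. All 12 were lower in 4 of 4 pairs.

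**Figure D2:**
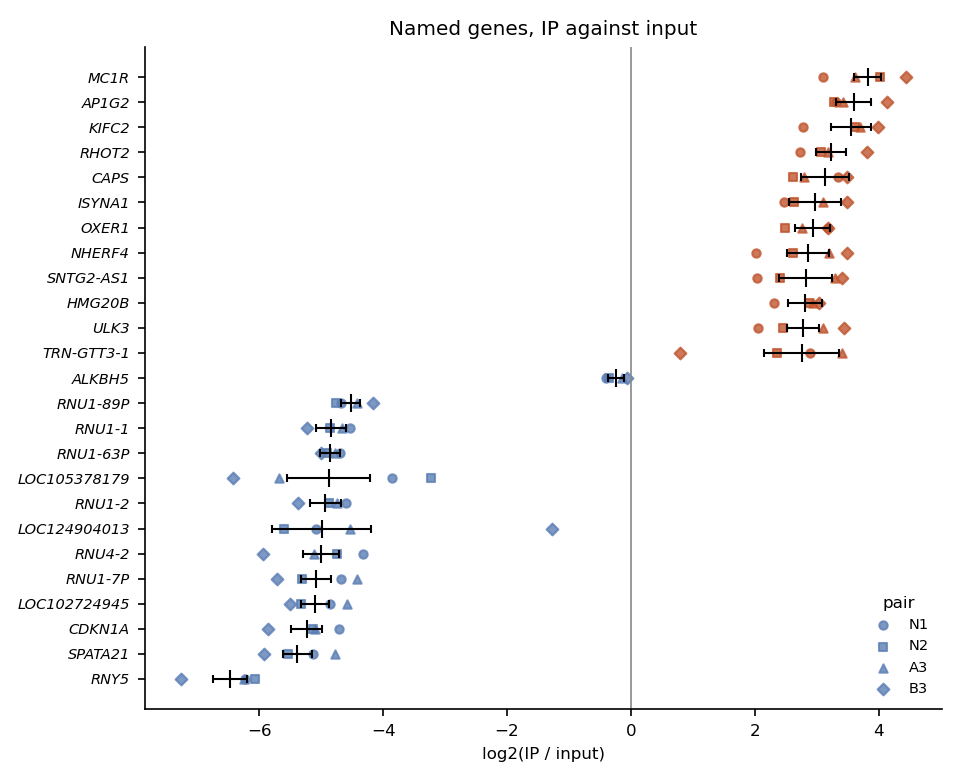
Log2 ratio of IP to input (x axis) for the 24 genes with the largest changes and for ALKBH5. Symbols give the 4 pairs, and the black mark with bars gives the fitted log2 fold change ± SE. MC1R stands highest at 3.82 and RNY5 lowest at -6.47. ALKBH5, at -0.24, turns to 0.09 with total counts only.

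The transcript of ALKBH5 itself, on chromosome 17 (18183828 to 18209954), was not gained in the IP of its protein. It gave 41.7 ± 3.34 CPM in the input and 35.7 ± 6.70 CPM in the IP (log2 fold change -0.24 ± 0.13, adjusted p = 0.238 in edgeR), lower in 4 of 4 pairs, and 0.09 (adjusted p = 0.782) with total counts only. In batch B1 alone it passed the threshold (-0.36, adjusted p = 0.00756 in edgeR), and over all alternatives the adjusted p ran from 0.00756 to 0.837. The insulin gene INS has no bin of its own because a readthrough gene overlaps it. Counted with its overlapping bins it gave 1034 ± 567 CPM in the input and 1297 ± 386 CPM in the IP, a log2 fold change of 0.47 ± 0.26 (adjusted p = 0.228 in edgeR), higher in 3 of 4 pairs.

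Beta cell identity genes, which define this cell type, were on balance higher in the IP. Of 23 members tested 6 rose, 0 fell and 17 did not pass (8 higher and 1 lower, adjusted over the list alone), and the median log2 fold change was 0.40. Among the 6 were ABCC8, the sulfonylurea receptor of the potassium channel that couples glucose to insulin release (0.94 ± 0.22), and the transcription factors PDX1 (0.94 ± 0.23), NKX2-2 (0.78 ± 0.13), NKX6-1 (0.78 ± 0.14) and PAX6 (0.46 ± 0.12). The set test (camera) gave adjusted p = 0.0248 with a preset correlation and adjusted p = 0.591 with an estimated correlation. Of all 16114 protein-coding genes 2762 rose and 1335 fell. Among the shortest (up to 10.7 kb) 31.2% rose, and among the longest (101.5 kb and over) 4.28%. Gene counts of this list and of the secretory, splicing and interferon lists were not compared with those of genes of the same span. Without N1 2 of the 6 members passed in edgeR, and without N2 only NKX2-2 did. All 6 passed without A3 or B3. Secretory granule and exocytosis genes had 5 members higher and 1 lower out of 23 (5 and 1 adjusted over the list alone), with a median of 0.44. STX1A, a membrane fusion protein, gave 1.98 ± 0.35, the release factor UNC13A 1.23 ± 0.30, the granule protein CHGB 1.14 ± 0.24 and VAMP2 1.02 ± 0.19, while RAB27A gave -0.69 ± 0.17. The set missed the threshold in camera (adjusted p = 0.0732, and 0.749 with an estimated correlation). It passed with the replicate block (0.0374), with total counts only (0.0143), without A3 (0.0384) and without B3 (0.036). Of the 6 members called, 3 passed without N1, and only CHGB passed without N2.

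Splicing regulators formed another group that was higher in the IP. Of 34 SR and hnRNP genes 12 rose and 0 fell (14 higher and 1 lower, adjusted over the list alone), with a median of 0.41. SRRM2 and SON, large proteins of nuclear speckles, gave 2.07 ± 0.17 and 1.00 ± 0.14, the kinase CLK2 1.32 ± 0.21 and HNRNPU 0.91 ± 0.16. Camera gave adjusted p = 0.00246, and 0.674 with an estimated correlation. Without N1 or N2 in turn 6 and 7 of the 12 passed in edgeR, and SRRM2, SON, CLK2, HNRNPU and HNRNPUL2 passed in every fit without 1 pair. All counts of HNRNPUL2 (2.45) lay in 2 bins, at 0.312 CPM in the input, so it had no value without its highest bins. Interferon and antigen presentation genes had 6 of 29 members higher and 0 lower (7 and 0 adjusted over the list alone). These were the signalling genes IRF7 (2.00 ± 0.39), STAT2 (from 24.6 to 78.9 CPM), TYK2 (1.54 ± 0.14), IRF3 (1.38 ± 0.18) and IRF9 (1.37 ± 0.26) and the editing enzyme gene ADAR (0.71 ± 0.16). The effector genes OAS1, MX1 and ISG15 gave 0.41, 0.24 and 0.19 with adjusted p of 0.387, 0.625 and 0.880 in edgeR. The set missed the threshold in camera (adjusted p = 0.0585, and 0.616 with an estimated correlation) and passed with the replicate block (0.0426), with total counts only (0.0319), without N1 (0.0316) and without N2 (0.0407).

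The genes of the m6A machinery went both ways. Of 20 tested, 3 were higher and 4 lower (3 and 5 adjusted over the list alone), and camera gave adjusted p = 0.244 (0.616 with an estimated correlation). METTL3, the catalytic subunit of the m6A writer (0.63 ± 0.14), its partner VIRMA (0.53 ± 0.17) and HNRNPA2B1 (0.60 ± 0.18) were higher. The other m6A demethylase FTO (-0.57 ± 0.14), the readers IGF2BP1 (-1.13 ± 0.34) and IGF2BP3 (-0.60 ± 0.15), and HNRNPC (-0.89 ± 0.13) were lower. Without N1 or N2 only 1 of these 7 passed in edgeR, HNRNPC, and 5 passed without A3, 6 without B3 and 3 with total counts only. Without its 4 highest bins HNRNPA2B1 missed the threshold (adjusted p = 0.0752 in edgeR) at a log2 fold change of 0.52, close to the 0.60 with them.

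The fixed list of nuclear non-coding RNAs was on balance lower in the IP, though not in all its members. Of 22 tested, 13 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -0.74. RPPH1, the RNA of RNase P, gave -4.03 ± 0.27, RMRP, the RNA of RNase MRP, -2.23 ± 0.14, and the telomerase RNA TERC -1.14 ± 0.28. SNHG8 (-2.49), SNHG12 (-2.26) and SNHG17 (-2.14) are hosts of snoRNAs and hold 88.1%, 73.1% and 70.6% of their counts in 4 bins, some of them within 100 nt of a snoRNA gene. Without those bins SNHG8 turned to 0.44 (adjusted p = 0.316) and SNHG12 and SNHG17 gave -0.53 (0.565) and -0.41 (0.143) in edgeR. SNHG5 (-0.04), SNHG15 (0.14) and TERC (-0.68) missed the threshold as well, and 9 of the 15 called members kept their call. The imprinted RNA MEG3 (1.39 ± 0.33) and TUG1 (0.89 ± 0.23) rose. NEAT1 gave 0.05 (adjusted p = 0.943 in edgeR), so the list's fall does not hold for nuclear non-coding RNA in general. The direction of MALAT1 depended on how shared bins were assigned, at 1.01 (adjusted p = 0.110, and 0.00013 with the replicate block) in its own bins and -0.25 (0.641) with overlapping bins included. Camera gave adjusted p = 2.7e-05 for the set, 0.0448 without the 4 highest bins of each gene, and 0.591 with an estimated correlation. Without N1 or N2 in turn 5 of the 15 called members passed in edgeR, and 9 passed with total counts only. RN7SK, the RNA that holds back a transcription elongation factor, gave -0.78 ± 0.34 (adjusted p = 0.136 in edgeR, and 0.0221 with the replicate block).

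All 13 mitochondrially encoded mRNAs had a higher level in the IP in 4 of 4 pairs. Of these 9 passed the test over all genes and 13 adjusted over the list alone, with 0 lower and a median of 0.90. ND2 gave 1.33 ± 0.22, ND5 1.30 ± 0.16, ND6 1.30 ± 0.15 and COX1 1.01 ± 0.23. Camera gave adjusted p = 2.12e-05, and 0.591 with an estimated correlation. Without N1 or N2 in turn ND2, ND5 and ND6 passed in edgeR and the other 6 did not. Cytosolic ribosomal protein genes had 1 member higher and 8 lower out of 77 (1 and 8 adjusted over the list alone), with a median of -0.11. Among the members called, the strongest loss was in RPS29 (-4.13 ± 0.60), with some of its 4 highest bins within 100 nt of the 7SL gene RN7SL1. RPL12 (-2.78 ± 0.38), RPS2 (-2.06 ± 0.23), RPL27A (-1.91 ± 0.31) and RPSA (-1.46 ± 0.30) followed, with some of theirs within 100 nt of snoRNA genes. Without the 4 highest bins RPL12 gave -0.02 (adjusted p = 0.963), RPS2 -0.48 (0.112), RPL27A -0.35 (0.244) and RPSA -0.30 (0.316) in edgeR, so these calls ended with those bins. RPS29 kept its call at -1.87 (adjusted p = 0.000233 in edgeR). Of the 9 members called, 4 passed without N1 and 4 without N2. Camera missed the threshold for this set (adjusted p = 0.0717, and 0.905 with an estimated correlation) but passed without A3 (0.000175) and without B3 (0.00547). Markers of other pancreatic and stromal cell types were scarce: 20 were tested, COL1A1 was higher (2.53 ± 0.41, at 1.25 CPM in the input) and 0 were lower (1 and 0 adjusted over the list alone). Their median of 0.20 and mean of 0.15 were positive while camera gave a downward direction (adjusted p = 0.933).

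Protein-coding genes that span over 100 kb were lower as a set. Of 3264 tested 574 fell and 141 rose (594 and 146 adjusted over the list alone), with a median of -0.29. Camera gave adjusted p = 2.03e-09, and 0.591 with an estimated correlation. The protein-coding genes were also put in 5 groups of near equal size by span. In the group of the shortest genes (up to 10.7 kb) 31.2% were higher and 0.745% lower. In that of the longest (101.5 kb and over) 4.28% were higher and 17.6% lower. The median log2 fold change of the shortest group was positive in all 4 pairs (0.29, 0.36, 0.85 and 0.86) and that of the longest negative (-0.11, -0.17, -0.42 and -0.38, in the order N1, N2, A3, B3). With total counts only, 380 of 26874 genes of all kinds were lower, so the calls of lower long genes depend on the scaling. Relative to other genes the set over 100 kb stayed downward with that scaling (camera, adjusted p = 1e-04). By chromosome, 31.6% of the protein-coding genes on chromosome 16, 29.3% on 19 and 27.5% on 17 were higher, against 3.83% on chromosome 18, 4.85% on 13 and 5.92% on 4. The median span of these genes was 21.9, 16.2 and 20.7 kb on the former and 63.7, 58.6 and 56.7 kb on the latter.

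With the replicate name as a block, 83 more members of the lists passed in edgeR besides the 97 of 464 called above, and 0 of those 97 were lost (long genes not counted). There were then 11 beta cell identity genes higher and 2 lower, 12 and 2 secretory granule genes, 5 and 6 m6A genes, 16 and 3 splicing regulators, 9 and 2 interferon genes, 3 and 16 nuclear non-coding RNAs, 2 and 14 ribosomal protein genes, and 13 and 0 mitochondrial mRNAs. Of other cell type markers 2 were higher and 1 lower.

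**Figure D3:**
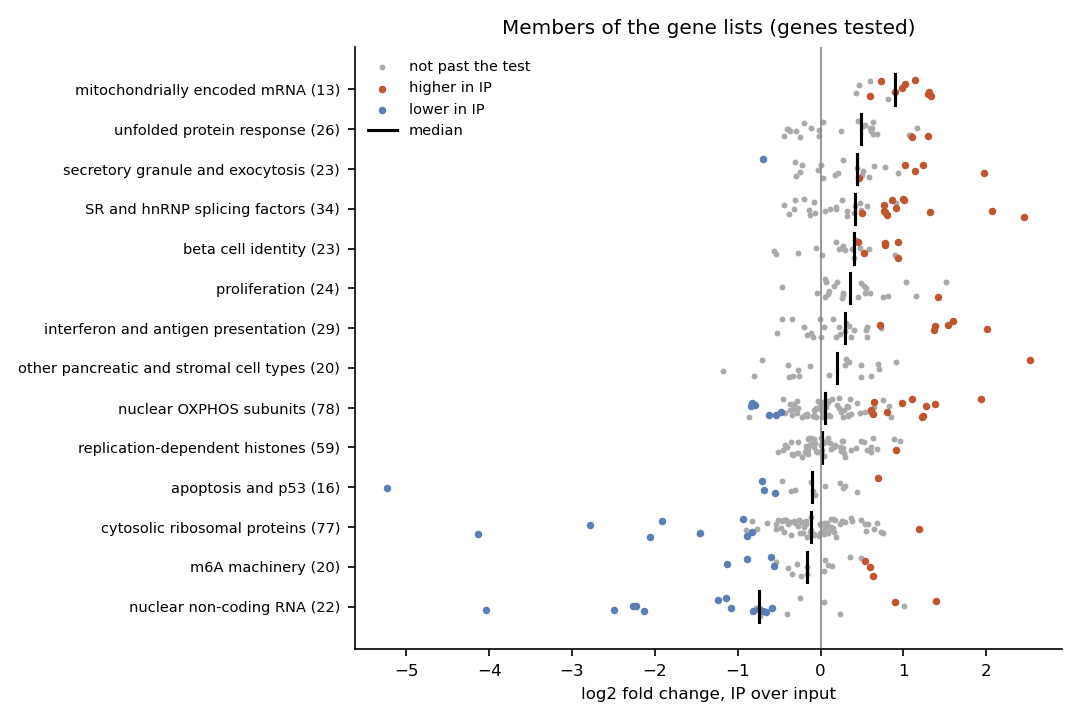
Log2 fold change of IP over input (x axis) for the tested members of 14 gene lists, with the number of genes tested in brackets. Each point is a gene, coloured where it passed the test, and the black line is the list's median. The mitochondrial mRNAs have the highest median (0.90) and the nuclear non-coding RNAs the lowest (-0.74).

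The next comparison concerned the deposited ALKBH5 peaks. The lists held 23082 peaks for N1, 23804 for N2, 35512 for A3 and 23979 for B3, with a median width of 100 nt. They covered 2.90, 3.16, 5.32 and 3.66 Mb. The score of a peak is the authors' IP count, with a median of 57.3, 66.3, 65.5 and 84.0 in the 4 lists. On the 25 chromosomes 84.5% ± 2.15 (SD, n = 4 lists) of the peaks lay in protein-coding genes, 2.85% ± 0.368 in long non-coding RNA genes and 5.80% ± 1.55 between genes. snRNA genes held 0.0329% ± 0.0170 of the peaks. Peaks of lists from the same batch shared more of their length (0.457 of the united length for N1 and N2, 0.436 for A3 and B3) than lists from different batches (0.272 to 0.319). Merged over the lists there were 45522 regions, of which 25531 came from 1 list and 5687 were present in all 4. With a p of at most 0.005 in each list, 487 regions were present in all 4.

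**Figure D4:**
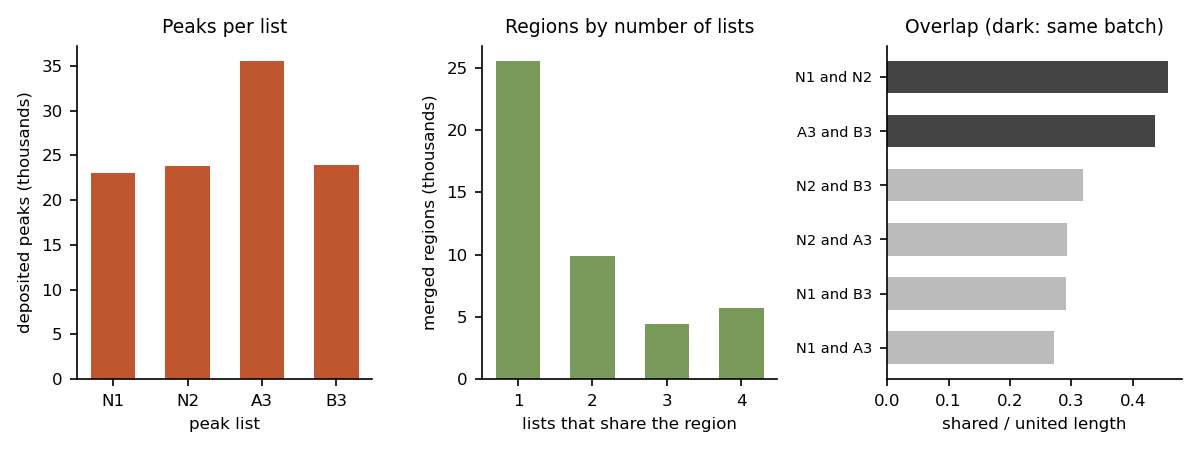
Left, number of deposited peaks in each list, with A3 at 35512 and the others between 23082 and 23979. Middle, merged regions by the number of lists that share them, 25531 in 1 list and 5687 in 4. Right, shared length over united length for each pair of lists, with pairs of the same batch in dark grey (0.457 and 0.436).

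Regions in all 4 lists lay in 1667 genes, 1284 of them protein-coding. The genes with the most such regions, chosen after their values were seen, were the ubiquitin ligases UBR4 (71), HECTD4 (52) and HUWE1 (44), the axonal kinesin KIF1A (43), the lipid kinase PI4KA (43) and the polycystin PKD1 (41). DST and MACF1 had 39 each, PRPF8 and VPS13A 36 each, and ABCC8 35. These numbers were not adjusted for depth or span, and the spans ran from 34.2 kb (PRPF8) to 497 kb (DST). PKD1 may share reads with annotated pseudogenes such as PKD1P4 and PKD1P5, so its number is uncertain. Among the fixed lists, 14 of 23 secretory granule genes had a region in all 4 lists, among them CHGA, CHGB, PTPRN, STX1A and VAMP2. So did 9 of 23 beta cell identity genes, among them ABCC8, INSM1, NKX6-1, PAX6, PDX1 and RFX6. That number lies within the range of gene sets of the same depth and span (3 to 11). Of 34 splicing regulators 15 had such a region, also within the range of their matched sets (6 to 16). Of 22 nuclear non-coding RNAs 4 had one, among them MALAT1 and MEG3. Of 20 m6A machinery genes 2 had one, HNRNPA2B1 and HNRNPC. Of 77 ribosomal protein genes 0 had one, although 40 had a region present in at least 2 lists.

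Counts in the peak regions were then compared between IP and input. The peaks were called by the authors on these same IP libraries, so this test is not independent evidence of binding. Of 19929 regions present in at least 2 lists, 17829 were higher in the IP and 71 lower (edgeR, adjusted p under 0.05), with a median log2 fold change of 1.80. Of the 5687 regions in all 4 lists 5606 were higher and 8 lower in the same fit, with a median of 2.14. Regions in protein-coding genes had a median of 1.84 (15547 higher and 4 lower of 16988), and those in tRNA genes of 1.46 (78 of 106 higher). Regions in ribosomal RNA genes had a median of -0.56, with 0 of 18 higher and 8 lower. The lower count was 111 with the replicate block, 26 without N1, 26 without N2, 147 without A3 and 116 without B3. Within batches, B1 alone gave 16280 higher and 378 lower regions and B2 alone 15940 and 5. Scaled on the regions themselves, the median was 0.00 and 2372 regions were higher and 2724 lower, so the direction is relative to the counts of all genes.

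The 8 regions of all 4 lists with the largest fold change lay in protein-coding gene spans, whether in exon or intron was not determined. The one in HDAC6, a cytoplasmic deacetylase, at chromosome X 48823646 to 48823795 went from 0.185 ± 0.0901 to 4.77 ± 2.04 CPM (SD, n = 4), a log2 fold change of 4.75 ± 0.46 (adjusted p = 4.68e-06 in edgeR). RHPN1 at chromosome 8 143381791 to 143381990 went from 0.278 ± 0.142 to 6.12 ± 1.54 CPM (4.54 ± 0.42), and OGDHL at chromosome 10 49735044 to 49735393 from 0.0985 ± 0.0193 to 2.50 ± 0.639 CPM (4.63 ± 0.39). IDUA at chromosome 4 1003349 to 1003498 gave 4.58 ± 0.57, and a region shared by BOP1 and SCX at chromosome 8 144268089 to 144268288 gave 4.72 ± 0.61. The other 3 lay in NPIPA6, NPIPA9 and NPIPA8 (5.01, 4.82 and 4.55), near-identical copies on chromosome 16 between which reads cannot be placed with certainty. They lay also in the spans of LOC131696449, PKD1P5-LOC105376752 and PKD1P4-NPIPA8, in the same order, so which gene they belong to is uncertain. All 8 were higher in 4 of 4 pairs.

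ABCC8, the beta cell identity gene with the most regions, spans 17392498 to 17476845 on chromosome 11. Its 35 regions of all 4 lists were higher in the IP without exception in edgeR, with log2 fold changes from 1.13 to 3.64 and a median of 1.81. That is more than the 0.94 of the gene as a whole, but the peaks were called on these same IP libraries, which favours such a difference. The highest bin held 3.97 CPM on average in the IP, and the highest bin of the input 0.707 CPM.

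**Figure D5:**
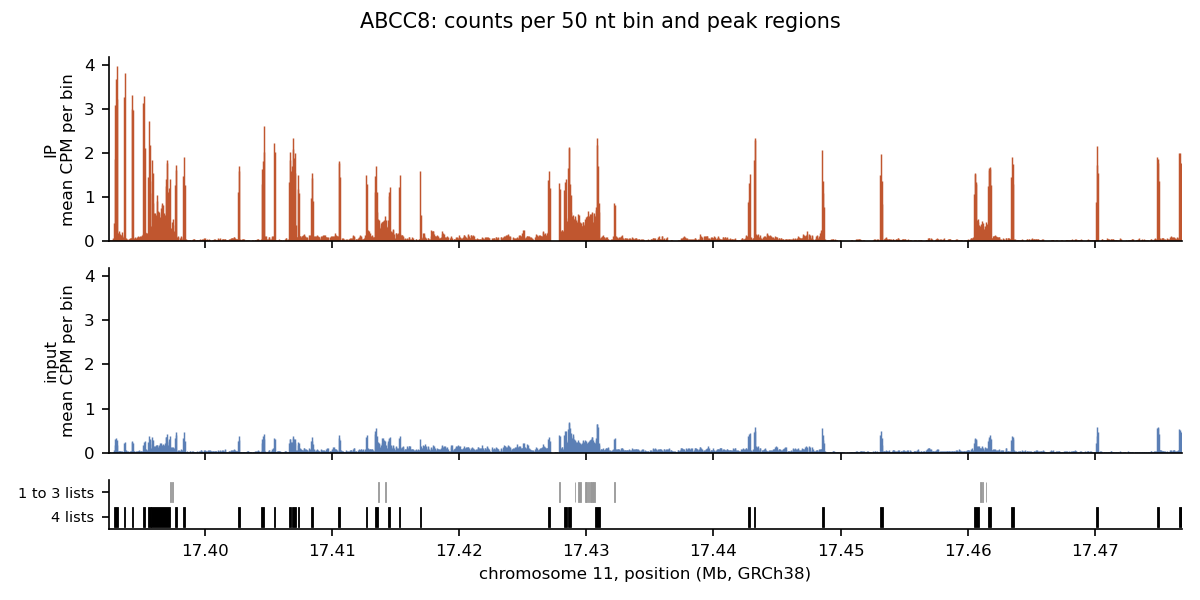
Mean CPM (of all counts of a library) per 50-nt bin over ABCC8 in the 4 IP and 4 input libraries on the same scale, above the merged peak regions, in black those of all 4 lists and in grey the others. The x axis gives the position on chromosome 11 in Mb (GRCh38). The 35 black regions coincide with narrow blocks of counts that reach 3.97 CPM in the IP.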

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

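The tests of tRNA genes, of RPPH1, RMRP and RN7SK and of the summed snRNA copies, and the refits without the 4 highest bins or with a span term, were chosen after the gene results were seen.

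Of 277 groups of 4 values examined, 16 had 1 library or list far from the other 3 by Dixon's criterion. Chance flags about 1 in 20 groups, so this number is near what chance gives. Of these, 11 concerned B3 and 5 A3, and 0 concerned N1 or N2. Where N1 and N2 lie close together the criterion can flag neither, so these numbers do not show that batch B2 was unusual. Many of the groups share libraries and are not independent.

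Among beta cell and secretory genes, PDX1 stood at 413 CPM in IP B3 against 180 to 218 CPM in the other IPs. STX1A stood at 148 CPM in input B3 against 54.3 to 63.7 CPM. UNC13A stood at 235 CPM in input B3 against 131 to 139 CPM, and at 682 CPM in IP B3 against 251 to 314 CPM. In the interferon list, IRF7 gave 131 CPM in IP B3 against 34.3 to 45.1 CPM, and the respiratory chain gene NDUFV1 129 CPM against 69.3 to 79.2 CPM. CAPS gave 46.2 CPM in IP B3 against 12.4 to 15.8 CPM, and SNTG2-AS1 18.0 CPM in input B3 against 4.99 to 7.01 CPM. The ALKBH5 transcript was at 46.7 CPM in input B3 and at 39.6 to 40.6 CPM in the other inputs.

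Among RNA processing and ribosomal genes, HNRNPUL2 gave 2.13 CPM in IP B3 against 1.54 to 1.62 CPM, and RPS29 1708 CPM in input B3 against 350 to 521 CPM. HNRNPDL gave 123 CPM in IP A3 against 82.8 to 83.6 CPM. The telomerase RNA TERC was lowest in IP A3, at 11.3 CPM against at least 19.6 CPM in the others. RPLP0 was lowest in input A3, at 48.6 CPM against 82.5 to 87.4 CPM, and so was VIRMA, at 37.2 CPM against 42.4 to 42.7 CPM. The peak list of A3 held 35512 peaks and the others 23082 to 23979.

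Sequences other than the 25 chromosomes were left out of the gene tests. On 1 unplaced sequence the IP libraries held 0.424% ± 0.174 (SD, n = 4) of their counts and the inputs 0.0732% ± 0.0183, a 5.79-fold difference, higher in 4 of 4 pairs. Of 107 such sequences with at least 0.01% of the counts, 89 were higher in the IP in 4 pairs. By their names several are versions of the same locus, such as the MHC region, so 89 is not a count of separate loci. Together the sequences outside the 25 chromosomes went the other way, from 38.4% ± 2.79 of the input counts to 35.9% ± 1.19 in the IP. Their share was lower in 4 of 4 pairs (exact permutation test, adjusted p = 0.157). The 3 sequences that held the most counts had lower means in the IP (0.897, 0.918 and 0.902 fold), each in 3 of 4 pairs. What these sequences encode was not analysed here.

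The first pattern weighed was the set of 5652 genes called higher or lower in the IP. Without the 4 highest bins of each gene 84.6% of these genes kept their direction and call, and with a smooth term of gene span 67.9% did, so neither a few bins nor gene span could be the whole cause. Of 35 splits of the 8 libraries into 4 and 4, only the real one (1 of 35) gave as many genes with the batch in the model, while the split by batch, which cannot carry that term, gave 2934 and points to a structure of the samples by batch. With no batch term in any split the real one gave 2505 and 2 of 35 gave as many, and the 8 splits that part all 4 pairs, where the real one gave 5652 and the highest other 0, are too few for a share under 0.05. Binding by ALKBH5 and RNA carried along by other bound proteins or by the beads both stay open, since no IP with another antibody was among the samples.

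For peak regions the real split gave 17900, 1 of 35 splits gave as many and the highest other, by batch, gave 204. The authors called the peaks on these IP libraries, which favours the real split, so this count says nothing about chance.

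The gene lists are less certain. The real split gave 5 shifted lists, 26 of 35 splits gave as many and the highest other gave 10, so chance cannot be excluded for the number of lists.

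The second pattern was the loss of small nuclear RNAs in the IP, with 34 of 45 snRNA genes lower. A loss of all short RNAs is argued against by the tRNA genes, whose median log2 fold change was 0.145. The snRNA genes without RN7SK and their annotated pseudogenes together fell from 3.18% ± 1.86 to 0.408% ± 0.249 of the counts. Their log2 ratios were -3.07 to -2.91 in the 4 pairs, so reads moved between these copies could not lower them. The U6 family went the other way in 4 of 4 pairs, from 0.0927% to 0.131% on average. Its log2 ratios were 0.11 and 0.39 in N1 and N2 but 2.0 and 3.1 in A3 and B3. Copies outside the annotation stay open, and RPPH1, RMRP and RN7SK, with a median of -2.23, decide nothing here, since they were chosen after their values were seen. An input rich in abundant ribonucleoproteins that ALKBH5 does not bind may explain the pattern and was not tested, nor was a difference in fragment size between IP and input.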

How the results depend on the processing

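The settings that left out the 4 highest bins, added a span term, gave shared bins to the shortest gene or scaled on the regions were chosen after the data were seen.

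By the rules used, a count stayed if it lay within 1.5 times of the main value. A share stayed if it was on the same side of the threshold or within the SD of the pair differences. Among the counts, shares and lists compared between IP and input, 136 values stayed by these rules and 45 moved. For all of these the cause was not tested, except where fewer regions or peaks entered by construction. The 86 share values all stayed by these rules, which do not require the same direction. With no class past the threshold, and with 3 against 3 libraries or 4 pairs too few to pass it, their side of the threshold says nothing about stability. The replicate block added 83 calls to the 97 among the 464 list members tested and lost 0.

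Of 416 values of the named genes, 384 kept their direction and side of the threshold. In 30 the direction held and the threshold was missed, 24 of them in batch B2 alone. ALKBH5 passed in batch B1 alone, and it turned from -0.24 to 0.0928 with total counts only. The 112 values of the named regions all kept their call.

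The number of genes higher in the IP, 3674, was 1871 without the batch term, 5815 with total counts only and 1179 to 4747 with a pair left out. The number lower, 1978, was 3526 with the replicate block, 634 without the batch term, 380 with total counts only and 291 to 3122 with a pair left out. It was 3207 with shared bins counted for each gene and 3073 with shared bins given to the shortest. Batch B2 alone gave 0 higher and 0 lower genes in edgeR, with 5881 at an unadjusted p under 0.05. Batch B1, with as many libraries, gave 4646 higher and 3162 lower, so the number of libraries alone does not account for it. These fits had no term for the pair. Across genes, A3 minus B3 correlated between IP and input with r = 0.578, and N1 minus N2 with r = 0.014. Whether this explains the contrast was not tested. In B2 alone 15940 peak regions were higher and 5 lower, although the peaks were called on these IP libraries. Genes that differed between batches were 0 of 27003 in edgeR and 133 in DESeq2.

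Gene lists higher in the IP numbered 3, and 0 with an estimated correlation, 6 with the replicate block, 5 with total counts only and 4 to 5 with a pair left out. Lists lower in the IP numbered 2, and 0 with an estimated correlation and 2 to 4 with a pair left out.

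Regions higher in the IP, 17829, were 5611 in a separate fit of those in all 4 lists, 33392 of those from any list and 2372 when scaled on the regions themselves. Regions lower, 71, were 111 with the replicate block, 19 without the batch term, 38 with total counts only and 26 to 147 with a pair left out. They were 378 in batch B1 alone, 5 in batch B2 alone, 8 of those in all 4 lists, 333 of those from any list and 2724 when scaled on the regions. That scaling sets the median region near 0 by construction.

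With a p of at most 0.005 in each list, 487 regions were present in all 4 lists instead of 5687 and 3466 in at least 2 instead of 19991. The lists then held 2502, 3420, 10787 and 5457 peaks for N1, N2, A3 and B3.

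Alternatives for exons, introns and the DRACH motif were not run, since no exons and no sequence were used here. On simulated data 10 of 100 regions changed 2-fold were found, against 53 of 100 genes, the latter drawn from well-covered genes.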

Other observations

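The refit without the 4 highest bins, named here for CDKN1A, was chosen after the gene results were seen.

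Respiratory chain genes of the nucleus went both ways in the IP: of 78 tested, 11 were higher and 6 lower (12 and 6 adjusted over the list alone), and camera gave adjusted p = 0.430, or 0.944 with an estimated correlation. The complex I genes NDUFV1 (1.93 ± 0.27), NDUFA11 (1.38 ± 0.22) and NDUFS8 (1.11 ± 0.19) were higher, and NDUFV2 (-0.83 ± 0.15), NDUFS4 (-0.79 ± 0.15) and the complex II gene SDHC (-0.84 ± 0.15) were lower. Without N1 8 and without N2 4 of the 17 passed, the latter NDUFV1, NDUFS8, ATP5F1D and NDUFA11. With total counts only, 11 of the 17 kept their call. Among unfolded protein response genes 2 of 26 were higher and 0 lower (2 and 0 adjusted over the list alone), CRELD2 (1.29 ± 0.30) and the chaperone HSP90B1 (1.10 ± 0.26), with camera at adjusted p = 0.177 (0.905 with an estimated correlation). Without N1 0 of these passed, and without N2 1 did. With the replicate block 10 unfolded protein response genes were higher and 4 lower, and 15 respiratory chain genes were higher and 9 lower.

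Of 24 proliferation genes the helicase MCM7 was higher (1.41 ± 0.28) and 0 were lower (1 and 0 adjusted over the list alone), and it missed the threshold without N2. With the replicate block 11 proliferation genes were higher and 1 lower. Camera gave adjusted p = 0.121 (0.905 with an estimated correlation), and the set passed with the replicate block (0.00324), without A3 (0.0101) and without B3 (0.00547). Of 16 apoptosis and p53 genes 1 was higher and 4 lower (2 and 4 adjusted over the list alone), with camera at adjusted p = 0.162 (0.591 with an estimated correlation). BAX was higher (0.69 ± 0.16), and XIAP (-0.71 ± 0.17), DIABLO (-0.54 ± 0.14) and CDKN1A were among the lower, the last through its 4 highest bins. Without N1 2 and without N2 1 of these 5 passed, and with total counts only 2 of the 5 kept their call. With the replicate block 2 genes of the list were higher and 6 lower. Of 59 replication-dependent histone genes H1-4 was higher (0.91 ± 0.28) and 0 were lower (0 and 0 adjusted over the list alone), and H1-4 missed the threshold without N1 or N2. With the replicate block 3 histone genes were higher and 0 lower. Camera gave adjusted p = 0.832 (0.962 with an estimated correlation), and 0.0384 downward without A3.

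With the TMM factors, the shortest protein-coding genes were more often called higher than lower in the IP (31.2% against 0.745%) and the longest more often lower (17.6% against 4.28%). With total counts only, 380 of 26874 genes of all kinds were lower, so the calls of lower long genes depend on the scaling. The set of genes over 100 kb missed the threshold with an estimated correlation (adjusted p = 0.591 in camera). A smaller share of sparsely covered bins in the IP, which would lower long genes if such bins lie mostly in them, was tested as a cause. In densely covered bins alone, set on the inputs of the other batch, the gap between the shortest and the longest of 5 groups of genes was 0.652, 0.767, 0.908 and 0.827 of the gap over all bins in N1, N2, A3 and B3. Since more than 0.652 of the gap stood in dense bins, sparse bins may explain a part of it and not the whole. Whether spliced RNA made up more of the IP than of the input stays open, as exons were not used here.

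A related hypothesis held that the IP was richer in unspliced RNA, which would raise sparse bins relative to dense bins of the same gene. The opposite was seen: the median log2 double ratio over protein-coding genes was -0.25 in N1, -0.33 in N2, -0.95 in A3 and -1.11 in B3, the highest being -0.2547. Flat background in the IP would raise sparse bins too. Its test, as set out beforehand, compared lower with higher genes, and the lower genes did have the larger ratios (-0.14, -0.24, -0.90 and -1.10, the highest -0.1424, against -0.54, -0.60, -1.23 and -1.35), as that explanation predicted. Sparse bins lost in both sets of genes in all 4 pairs, which a flat background alone does not give, so the outcome set out beforehand was not a sufficient test.

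Peak regions were then compared with chance for genes of the same depth and span. Among 46 beta cell identity and secretory granule genes 23 had a region in all 4 lists, and 10000 matched gene sets had 12.5 on average (7 to 18 in the middle 95%, permutation adjusted p = 0.0028). Secretory granule genes carried this, with 14 of 23 against 5.57 (2 to 9, permutation p = 0.0002, the smallest two-sided value they can give, adjusted p = 0.0014). Beta cell identity genes had 9 against 6.90 (3 to 11, adjusted p = 0.568 in the permutation test), and splicing regulators 15 of 34 against 11.2 (6 to 16, adjusted p = 0.345). Ribosomal protein genes had 0 of 77 against 16 to 30 (adjusted p = 0.0014) and histone genes 0 of 59 against 6.89 (3 to 12, adjusted p = 0.00336). The 13 mitochondrial mRNAs had 0 against 6.58 (3 to 10, adjusted p = 0.0028), but a single A3 peak of 16569 nt merged all peaks of that chromosome into 1 region, so their count is fixed by the merging. Read depth and span are therefore unlikely to be the whole cause for the secretory granule genes, with 23 genes over both lists above the matched range, and the GC content and exon length of these genes were not tested.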
